A study of Mus musculus with 16 samples.

How the data were processed

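H3K27ac was measured by chromatin immunoprecipitation and sequencing in MPP, CDP, cDC and pDC of C57BL/6 mice, with 2 libraries per cell type. Per the labels, chromatin of 1000000 cells was sheared to 200 to 400 bp and precipitated with 1 µg of antibody. Besides the protocol and processing, the labels give strain, cell type and antibody only, so sex, animal and culture are not given in the sources used here. Input libraries and RNA samples were not analysed here.

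Per the labels, reads were aligned with BWA 0.6.1 to the mouse genome build mm9. The series title names THOR, a caller of differential peaks that uses replicates. The authors' deposited lists hold, for each region, its bounds, a direction, signals of the 2 libraries of each group, and −log10 of a p-value. The authors' deposited signals are in a unit other than read counts: whole numbers scaled per library and separately in each list. Levels were therefore compared only within a list, and the read depth is unknown. The p-values and the values per region are the authors'. No correction or threshold is stated, and −log10 p starts at 0.30, so that 81.0% to 87.7% of the regions of a list have a p under 0.05. A last column without a name was not used.

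Which values belong to which group was taken from the order of cell types in the list names. It was checked on regions with identical bounds in 2 lists. Values of the same group and place differed by a constant factor of 0.807 to 1.14, with an SD of at most 0.058 on the log2 scale in 10 pairs. The other 86 pairs had an SD of at least 0.45. MPP appears in 1 list only, so its place rests on the list name and on elimination. The values carry no replicate number, and libraries are called first-listed and second-listed. Nothing in the labels says whether the 2 libraries of a cell type came from separate animals or cultures.

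Ratios are those of group means after adding a pseudocount of 1 to the means. Ratios of stretches are those of signals summed over their regions. A region had separate libraries when both values of a group lay above both of the other. The combined rule asked for a ratio of at least 2, a deposited −log10 p of at least 10 and separate libraries, and was chosen after seeing the data. A two-sided exact permutation test of 2 against 2 cannot go below 0.333. A test per region that shares variance across regions was not run. Coordinates are 1-based.

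Regions were named by a rule fixed before the data were examined. In each comparison and direction, among regions with separate libraries and a higher group mean at or above the median of the direction, it takes the 5 with the largest log2 ratio and the 5 longest stretches after joining regions less than 1 kb apart. Of the 80 items this gives, a selection is given in the text, made after their values were seen. The wording allows the joining to use these regions or every region of a direction. Both were computed, and the first was taken after both had been seen. Of the 40 stretches of the other reading, 20 overlap a named one, 6 are on the Y chromosome and 9 lack separate libraries. In 11 of the 40 single regions the lower group is listed at 0, and no ratio is given.

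A region was followed into a second list by the direction of the second-list regions that cover most of it. A stretch was followed by the signals summed over every region of the second list within it. A region not covered by a second list is one where that list has no region, which does not show equal signal. Overlap was compared with 100 random shifts along the chromosomes, with independent lists, and with 20000 simulated unchanged regions whose groups share 2 libraries, and with 2000000 for the combined rule without its p-value. For the sex chromosomes, signal was given per 1000000 units of autosomal signal of the library in the listed regions and averaged over the lists that hold it. On simulated values made from the MPP and CDP list, log2 ratios of 0, 1 and 3 were recovered as 0, 0.99 and 2.97 in 5000 regions each, with separate libraries in 32.2%, 96.2% and 100% of them.

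Alternatives fixed before the data were examined were a stricter p, a minimum length of 500 bp, joining, a ratio of at least 2, separate libraries, autosomes only, pseudocounts of 0.5 and 5, leaving out each library for the median ratios, and other measures of overlap. The combined rule, adjusted p-values, leaving out touching regions, equal autosomal totals, and leaving out each library for the counts were added after seeing the data. Autosomal totals are sums of a library's signal over the autosomal regions of a list, not over the whole genome. Because these regions were called as differing, equal totals can also remove part of a true net difference. An annotation of mm9 was not used here, so no gene was named from its position and 17 gene lists fixed beforehand were not tested. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.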

Results

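H3K27ac, a histone acetylation found at active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in 4 mouse cell types of the dendritic cell lineage on the C57BL/6 background. Multipotent progenitors (MPP) precede common dendritic cell progenitors (CDP), which give rise to classical dendritic cells (cDC) and plasmacytoid dendritic cells (pDC). Each cell type had 2 H3K27ac libraries, so that 8 libraries entered the comparisons. The 4 input and 4 RNA samples were not analysed here. The deposited data were 4 lists of regions called as differing between a pair of cell types, with the signal of each of the 4 libraries in every region. The lists covered MPP and CDP, CDP and cDC, CDP and pDC, and cDC and pDC, which follow the steps of differentiation and the split into the mature cell types. The read depth of the libraries is unknown, because the listed signals had been scaled.

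Libraries of the same cell type ranked regions alike but differed in level. Across regions, which are not independent replicates, Pearson's r between the log2 signals of the 2 libraries of a cell type ran from 0.926 for MPP to 0.950 for pDC in the list with cDC. The median SD between the 2 libraries was 0.28 on the log2 scale for MPP and 0.26 for CDP in their common list. It was 0.39 for cDC and 0.26 for CDP in theirs, and 0.22 for pDC in the list with CDP. The second-listed cDC library exceeded the first by a median of 0.50 on the log2 scale in each of its lists, the largest such offset of any cell type. With these offsets removed, the SD in the CDP and cDC list was 0.24 for cDC and 0.24 for CDP. The second-listed MPP library lay below the first, with a median difference of -0.31.

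In the step from MPP to CDP, H3K27ac was lost and gained at similar numbers of places, and the stretches named by the rule were 11.25 to 15.7 kb long. Joining every region of a direction gave stretches of 16.05 to 49.95 kb in this list. The list held 33029 regions higher in MPP and 27787 higher in CDP, with median ratios of 1.43 and 1.40. With the autosomal totals of the libraries over the listed regions made equal, 29795 were higher in MPP and 31021 in CDP. A combined rule was applied to every list, asking for a ratio of at least 2, a deposited −log10 p of at least 10, and both libraries of the higher group above both of the lower. It kept 6745 regions higher in MPP, with a median ratio of 3.39, and 5161 higher in CDP, with a median ratio of 3.25. With equal totals it kept 6092 and 5903. Of the stretches higher in MPP, the steepest was on chromosome 11 from 87601901 to 87616250 (mm9), where the MPP libraries had summed signals of 21694 and 16307 against 773 and 1015 in CDP, a 21.2-fold difference. Chromosome 10 from 79335801 to 79349850 was 2.97-fold higher in MPP, and chromosome 7 from 142779501 to 142795200 was 2.02-fold higher. On chromosome 6, the stretch from 52168001 to 52181100 was 1.70-fold higher in MPP. Of the stretches higher in CDP, chromosome 6 from 65534451 to 65548150 differed most, with 13716 and 11404 in CDP against 4223 and 3193 in MPP, a 3.39-fold difference. Chromosome 8 from 125445551 to 125460150 was 1.95-fold higher in CDP.

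Single regions were chosen for the largest ratios and stretches for length, so larger ratios between MPP and CDP follow from the choice. Ratios are on the scale of signal plus 1. Chromosome 12 from 100797351 to 100798300 had signals of 446 and 421 in MPP against 0 and 8 in CDP, an 86.9-fold difference. Chromosome 8 from 13964201 to 13965300 had 665 and 482 in MPP against 3 and 9 in CDP. In the other direction, chromosome 1 from 108241351 to 108242100 was listed at 0 in both MPP libraries and at 453 and 275 in CDP. Chromosome 2 from 5661851 to 5662700 had 1 and 0 in MPP against 237 and 398 in CDP. The region with the largest ratio in favour of MPP, on the X chromosome from 100676501 to 100678500, rested on a single library, with 9 and 2739 in MPP against 5 and 7 in CDP. Over all regions of the list the median log2 ratio of CDP to MPP was -0.12. It was 0.091 without the first-listed MPP library and 0.017 with the autosomal totals of the libraries over the listed regions made equal.

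**Figure D1:**
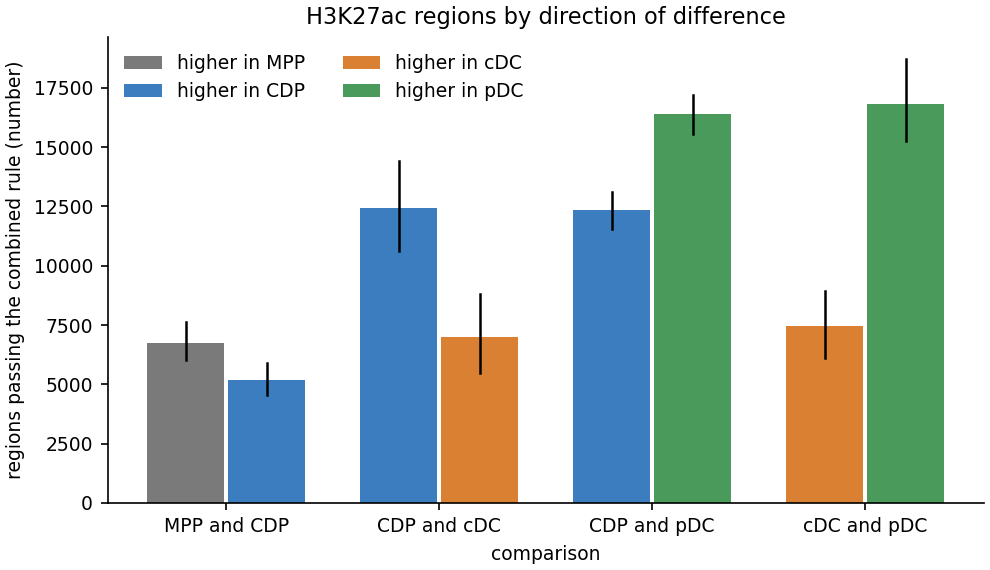
Number of H3K27ac regions passing the combined rule (vertical axis) in each of the 4 comparisons (horizontal axis), with a bar for each direction coloured by the cell type with the higher signal. Black lines run from the lowest to the highest count with each of the 4 libraries of a list left out in turn. The deposited p-value, from all 4 libraries, was kept for these counts. The 16803 regions higher in pDC than cDC stand above the 7446 higher in cDC.

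From CDP to cDC, more places lost H3K27ac than gained it as deposited, and the longest gained stretch was on chromosome 17. With the autosomal totals of the libraries over the listed regions made equal, 42086 regions were higher in CDP and 34779 in cDC. Without the first-listed cDC library the median log2 ratio over all regions turned to 0.052, so its sign depended on that library. The second-listed cDC library, which then stood alone, lay a median of 0.50 above the first on the log2 scale. Without the first, the combined rule still kept 10613 regions higher in CDP against 8818 higher in cDC. The deposited p-value in that rule still came from all 4 libraries. The list held 43871 regions higher in CDP and 32994 higher in cDC, with median ratios of 1.63 and 1.42. These are the deposited directions, and in 399 regions the group means did not lie in the called direction. The combined rule kept 12450 regions higher in CDP, with a median ratio of 4.21, and 6994 higher in cDC, with a median ratio of 3.60. With equal totals it kept 12052 and 7626. The longest stretch higher in cDC, on chromosome 17 from 34418151 to 34447500, had signals of 56614 and 84580 in cDC against 7950 and 6766 in CDP, a 9.59-fold difference. Close to it, chromosome 17 from 34393201 to 34408400 had 30037 and 41869 in cDC against 3281 and 2366 in CDP, a 12.7-fold difference. Chromosome 5 carried a pair of further stretches, from 143662551 to 143675950 with a 2.09-fold and from 114275851 to 114292050 with a 2.04-fold higher signal in cDC.

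The stretches named as higher in CDP were 19.75 to 42.9 kb long, against 13.35 to 29.35 kb for those higher in cDC. Joining every region of a direction gave up to 60.35 kb for CDP and 35.7 kb for cDC. Chromosome 11 from 86401451 to 86444350 had 79246 and 67541 in CDP against 14079 and 27224 in cDC, a 3.55-fold difference. Chromosome 5 from 3486401 to 3506150 was 5.26-fold higher in CDP, and chromosome 13 from 63341351 to 63362950 was 4.22-fold higher. At 2 further stretches on chromosome 13, from 23637601 to 23677100 and from 23830601 to 23857500, CDP exceeded cDC by 1.78-fold and 1.76-fold. Among single regions, chromosome 11 from 45869251 to 45872800 had 2708 and 4695 in cDC against 24 and 18 in CDP, a 168-fold difference. Chromosome 13 from 48610751 to 48612750 had 740 and 1535 in cDC against 8 and 0 in CDP. Higher in CDP, chromosome 3 from 115344351 to 115346450 had 1210 and 1677 against 6 and 4 in cDC, and chromosome 19 from 29899301 to 29900150 had 404 and 432 and was listed at 0 in both cDC libraries. The median log2 ratio of cDC to CDP over all regions was -0.17. It was -0.093 with equal totals and 0.052 without the first-listed cDC library.

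From CDP to pDC, the balance of gains and losses in H3K27ac depended on the scaling. As deposited, the list held 34843 regions higher in CDP and 35115 higher in pDC, covering 27.8 Mb and 35.8 Mb. With the autosomal totals of the libraries over the listed regions made equal, 40882 were higher in CDP and 29076 in pDC. Those regions were called as differing, so this does not settle which side has more. The deposited median ratio was 2.17 for regions higher in pDC and 1.77 for those higher in CDP. The combined rule kept 16417 regions higher in pDC, with a median ratio of 5.84, and 12351 higher in CDP, with a median ratio of 4.85. With equal totals it kept 14565 and 14546. A pair of neighbouring stretches on chromosome 8 were the longest gains named. From 123289101 to 123326400 the pDC libraries had 57194 and 59654 against 3360 and 6706 in CDP, an 11.6-fold difference, and from 123258751 to 123287850 they had 47131 and 43724 against 4223 and 6292, an 8.64-fold difference. Chromosome 7 from 63018151 to 63042650 was a single region of 24.5 kb with 37249 and 40985 in pDC against 1540 and 2350 in CDP, a 20.1-fold difference. Chromosome 15 from 85997151 to 86017350 was 6.20-fold higher in pDC and chromosome 16 from 91442901 to 91467700 was 5.15-fold higher.

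In the opposite direction, several stretches that lost signal from CDP to cDC were also lower in pDC. Chromosome 5 from 3488901 to 3506100 had 24866 and 23608 in CDP against 2755 and 2544 in pDC, a 9.14-fold difference. Chromosome 11 from 86388601 to 86412750 was 3.64-fold higher in CDP. On chromosome 13, the stretch from 23621351 to 23649750 was 3.26-fold and that from 23828701 to 23857400 was 2.57-fold higher in CDP. Among single regions, chromosome 1 from 74846601 to 74848000 had 1121 and 1215 in pDC against 1 and 0 in CDP. Chromosome 13 from 48610501 to 48612550 had 2963 and 3256 in pDC and was listed at 0 in both CDP libraries. Chromosome 12 from 33725001 to 33727400 had 1960 and 1296 in CDP against 3 and 4 in pDC, a 362-fold difference. The median log2 ratio of pDC to CDP over all regions was 0.04, and it was -0.26 with the autosomal totals made equal. It was -0.071 without the first-listed CDP library and -0.083 without the second-listed pDC library.

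**Figure D2:**
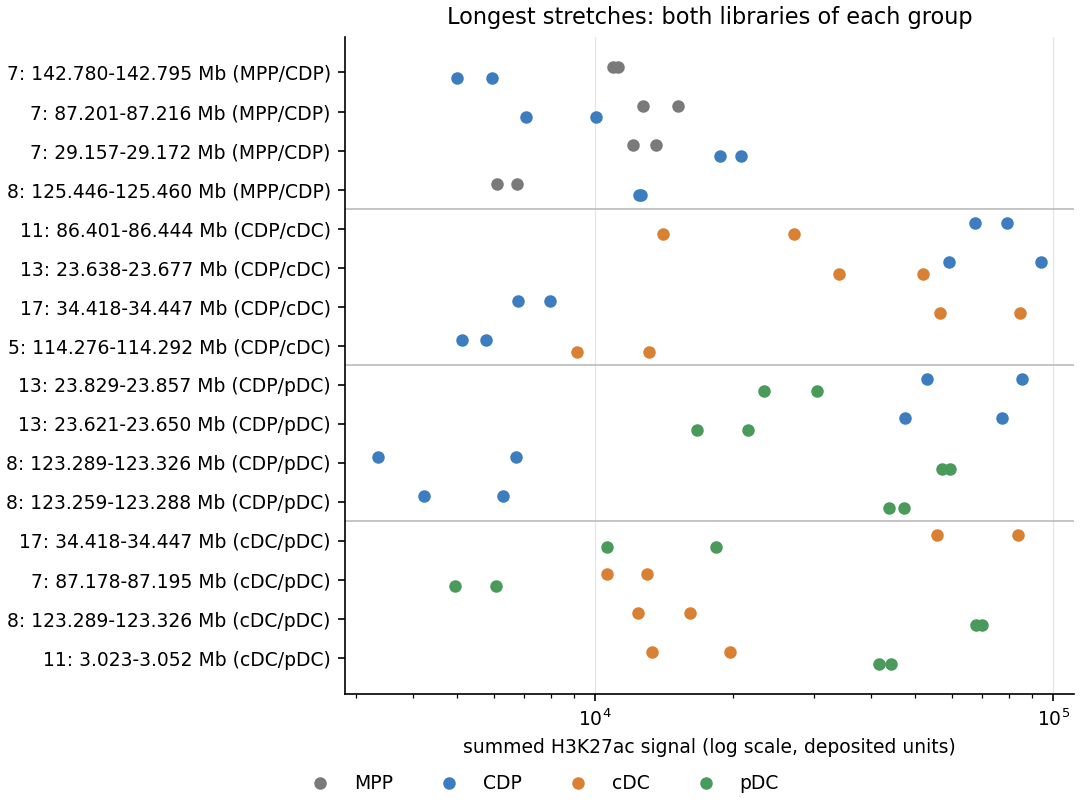
Summed H3K27ac signal of each library in the 2 longest stretches of each comparison and direction (horizontal axis, log scale, deposited units), with a row for each stretch (vertical axis, mm9 position and the 2 cell types of the list) and a point for each library, coloured by cell type. The rule that chose the stretches asks for both libraries of a group above both of the other, so the points of the groups do not overlap.

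Between cDC and pDC, the side with more of the differing regions depended on the scaling. As deposited, the list held 37832 regions higher in pDC, covering 39.5 Mb, and 28487 higher in cDC, covering 21.9 Mb. With the autosomal totals of the libraries over the listed regions made equal, 26241 were higher in pDC and 40078 in cDC. Those regions were called as differing, so equal totals can also remove part of a true net difference. The combined rule kept 16803 regions higher in pDC, with a median ratio of 6.03, and 7446 higher in cDC, with a median ratio of 4.01. A stretch on chromosome 8 was the longest named as higher in pDC, while joining every region gave a longer stretch of 74 kb on chromosome 11 from 3022501 to 3096500. The chromosome 8 stretch had 67865 and 70070 in pDC against 12371 and 16085 in cDC from 123289151 to 123326450, a 4.85-fold difference. The neighbouring stretch from 123258751 to 123286150 differed 3.14-fold. Chromosome 7 from 63018151 to 63042700 was 11.1-fold higher in pDC, chromosome 16 from 91442851 to 91467700 was 3.23-fold higher, and chromosome 11 from 3022501 to 3051850 was 2.60-fold higher. The chromosome 17 stretches were higher in cDC. From 34418251 to 34447450 the cDC libraries had 55800 and 83810 against 10589 and 18380 in pDC, a 4.82-fold difference, and from 34393251 to 34407750 the difference was 6.42-fold. Chromosome 6 from 65533901 to 65547600 was 6.36-fold higher in cDC, and chromosome 7 from 87177751 to 87194850 was 2.14-fold higher.

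Single regions were again chosen for the largest ratios. Chromosome 3 from 98227051 to 98228150 had 523 and 665 in pDC against 0 and 1 in cDC, and chromosome 3 from 115437201 to 115438150 had 517 and 753 in pDC and was listed at 0 in both cDC libraries. Chromosome 2 from 165230701 to 165231800 had 663 and 742 in cDC against 0 and 3 in pDC. The share of regions higher in pDC was 57.0% as deposited and 39.6% with the autosomal totals of the 4 libraries made equal, which changed the combined rule's counts to 14275 higher in pDC and 10633 higher in cDC. The median log2 ratio of pDC to cDC was 0.20 as deposited, -0.26 with equal totals and -0.017 without the first-listed cDC library.

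The regions are those of the authors' deposited lists, and no test per region was added here, including any that shares variance across regions. A two-sided exact permutation test of 2 libraries against 2 cannot give a p below 0.33. The 2 libraries of the higher group lay above both of the other group in 51.3% of the regions higher in cDC than CDP and in 79.1% of the regions higher in pDC than CDP, the lowest and highest shares as deposited. With equal totals these were 72.7% and 67.3%, and the lowest and highest were 56.7% for MPP over CDP and 94.9% for cDC over pDC. Chance gives 33.3% for regions not chosen for a difference, whereas these were called from the same 4 libraries.

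The same places could be followed from list to list. Of the 6745 regions higher in MPP than CDP under the combined rule, 31.3% lay mainly in regions that were higher in CDP than cDC, while 13.8% lay in regions higher in cDC. The other 54.9% were not covered by any region of the CDP and cDC list. Over all 33029 regions higher in MPP the shares were 53.5%, 27.4% and 19.1%. The covering regions were taken whatever their ratio or p-value, and their bounds often differed. Of the 5161 regions higher in CDP than MPP, 66.5% lay in regions higher in CDP than cDC and 33.5% in regions higher in cDC. In the CDP and pDC list, 68.3% of these 5161 regions lay in regions higher in CDP and 31.4% in regions higher in pDC. Over all 27787 regions higher in CDP than MPP, the shares were 68.5% and 31.5% in the CDP and cDC list. In the CDP and pDC list they were 68.0% and 31.6%. Of all regions of these 2 lists, 57.1% and 49.8% were higher in CDP. At chromosome 6 from 65533901 to 65548150, the gain of 3.39-fold from MPP to CDP over 12.75 kb was followed by a 9.51-fold lower signal in pDC than CDP over 12.85 kb. Against cDC, CDP was 1.43-fold higher over 10 called regions, of which 10.6 kb were higher in CDP and 2.75 kb in cDC. The stretch on chromosome 11 from 87601901 to 87616250 that was higher in MPP was not covered by any region of the other 3 lists.

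Regions that differed between CDP and cDC were also read in the CDP and pDC list, which shares the CDP libraries. Of the 12450 regions higher in CDP than cDC, 73.5% lay in regions higher in CDP than pDC and 10.4% in regions higher in pDC. Of the 6994 regions higher in cDC than CDP, 48.7% lay in regions higher in pDC than CDP, 8.68% in regions higher in CDP, and 42.7% in none. Without the combined rule, 61.2% of the 43871 regions higher in CDP lay in regions higher in CDP than pDC and 21.6% in regions higher in pDC. Of all 32994 regions higher in cDC, 49.7% lay in regions higher in pDC, 28.4% in regions higher in CDP and 22.0% in none. The difference between losses and gains was not tested. Ratios of the same stretch in different lists rest on different called lengths. In the chromosome 17 stretch from 34418151 to 34447500, cDC was 9.59-fold higher than CDP over 28.5 kb, and pDC was 2.04-fold higher than CDP over called regions of which 11.6 kb were higher in pDC. In the chromosome 8 stretch from 123289101 to 123326450, cDC was 2.72-fold higher than CDP over 22.95 kb and pDC was 11.6-fold higher than CDP over 37.1 kb. On chromosome 6 from 52168001 to 52181100, the signal that was lower in CDP than MPP was a further 6.81-fold lower in cDC than CDP over 10.85 kb and 2.40-fold lower in pDC than CDP over 10.35 kb.

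**Figure D3:**
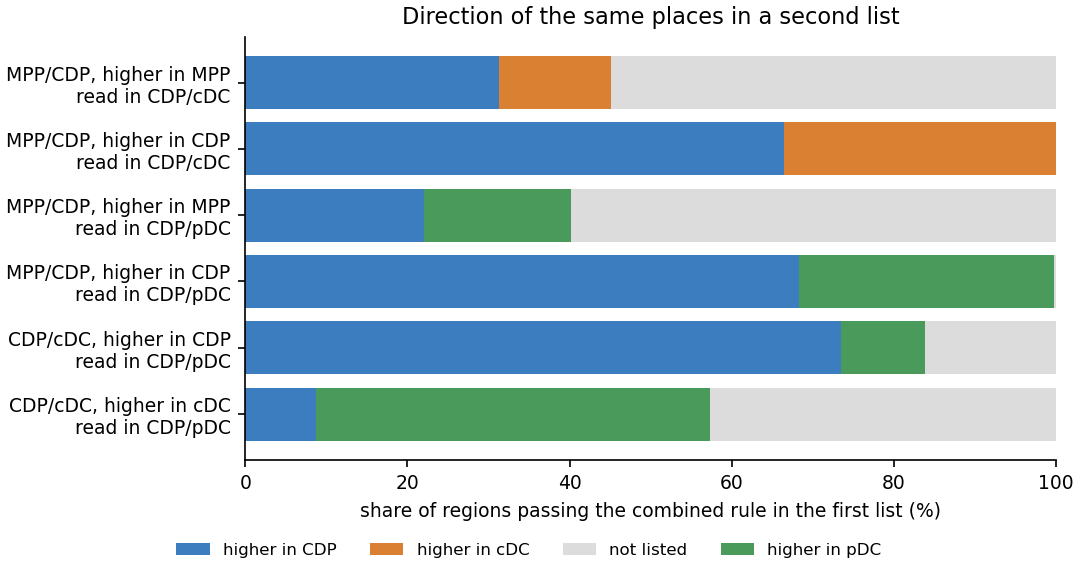
Share of regions passing the combined rule in a first list, in percent (horizontal axis), by the direction of the second-list region that covers most of them. Rows (vertical axis) give the first list, the cell type with the higher signal in it, and the second list; grey marks regions that no region of the second list covers, 54.9% in the top row.

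Lists that share a cell type share its libraries, and this alone places that cell type on the same side in both (higher in both or lower in both). Beside each share of base pairs stand the shares for independent lists, for simulated unchanged groups that share 2 libraries, and for such groups at ratios as large as those listed. For CDP in the lists with cDC and pDC the share was 74.2%, against 51.7%, 66.5% and 94.2%. For CDP in the lists with MPP and cDC it was 50.3%, against 49.7%, 66.5% and 89.9%, and with MPP and pDC it was 54.2%, against 50.1%, 67.3% and 95.1%. For cDC in the lists with CDP and pDC it was 61.7%, against 49.9%, 66.8% and 92.5%. For pDC in the lists with CDP and cDC it was 85.2%, against 56.8%, 66.3% and 96.3%. Each of these shares over all regions lay below that of unchanged groups at the listed ratios. Under the combined rule in both lists they were 91.7% for CDP with cDC and pDC, 57.2% for CDP with MPP and cDC, 65.6% for CDP with MPP and pDC, 78.5% for cDC and 98.6% for pDC. Simulated unchanged groups with a ratio of at least 2 and separate libraries in both lists gave 100% in each pair, from 211 to 489 simulated regions. An unchanged region reaches large ratios in both lists mainly when its shared libraries deviate by chance, which puts the cell type on the same side. The simulated shares at the listed ratios and under this choice were thus largely fixed by the selection. A listed share below them does not show weaker agreement than in unchanged groups. Part of any excess over independent lists may come from the shared libraries. The shared libraries were not divided between the lists, since each list would then have held 1 of them.

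The lists covered largely the same parts of the genome. Of the regions in the MPP and CDP list, 89.6% overlapped a region of the CDP and cDC list by at least 1 bp and 87.1% a region of the CDP and pDC list. Of the regions in the CDP and cDC list, 80.7% overlapped the CDP and pDC list and 75.3% the cDC and pDC list. Of the regions in the CDP and pDC list, 85.2% overlapped the cDC and pDC list. In 100 random shifts of a list along the chromosomes, the overlap was never above 4.82%. Within the 85.7 Mb called in any list, independent lists would share 35.9, 36.9, 46.0, 44.5 and 45.6 Mb, in the same order. The lists shared 42.4, 40.3, 47.5, 43.8 and 52.5 Mb. The 85.7 Mb are the union of these same lists, so a large overlap of independent lists was built in. This comparison therefore cannot show how much of the overlap is that of independent lists.

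Signal on the sex chromosomes separated single libraries of the same cell type. The X chromosome region around 100676501 to 100678500 had a signal of 68.7 per 1000000 units of autosomal signal in the second-listed MPP library, 67.5 in the second-listed cDC library and 89.0 in the first-listed pDC library. The other 5 libraries had between 0.048 and 0.27. Regions in the first 1 Mb of the Y chromosome had 671 on the same scale in the first-listed MPP library and 0 in the second. The CDP libraries had 681 and 713, the cDC libraries 743 and 244, and the pDC libraries 21.7 and 565.

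**Figure D4:**
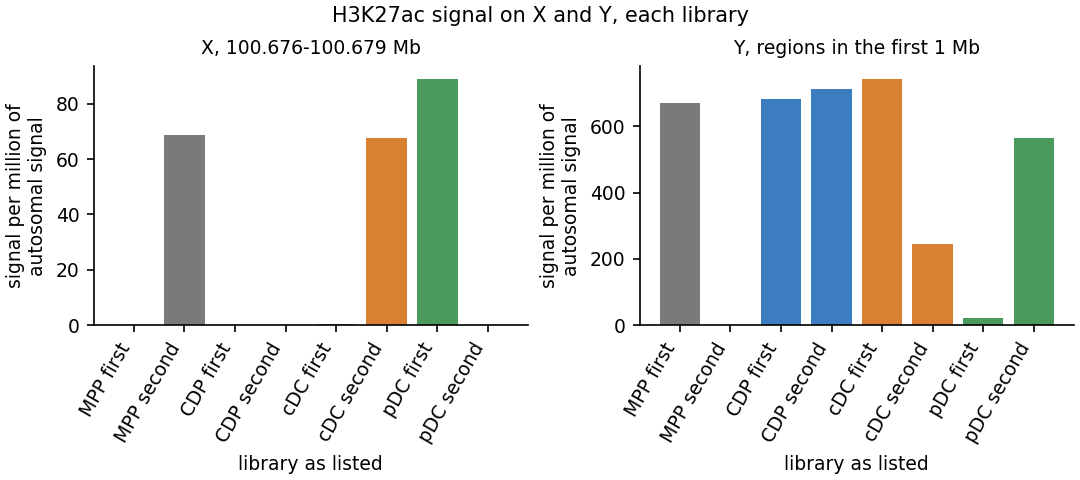
H3K27ac signal per 1000000 units of autosomal signal (vertical axes) in the X chromosome region (left) and in regions of the first 1 Mb of the Y chromosome (right), with a bar for each of the 8 libraries in the order listed (horizontal axes), coloured by cell type and averaged over the lists that hold the library. The second-listed MPP, second-listed cDC and first-listed pDC libraries stand at 67.5 to 89.0 on the left.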

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

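The counts in this part, their rule and the libraries left out were chosen after the results were seen. At 273 places H3K27ac was higher in cDC than CDP and lower in pDC than CDP, and at 699 places it was lower in cDC and higher in pDC, with the combined rule met in both lists. They were flagged because cDC and pDC differ from CDP in opposite directions. The combined rule asks for both libraries of a group on the same side, so that agreement was fixed by the choice of places. The difference between cDC and pDC was not tested. The count of 273 depended on the cDC libraries, at 456 without the first-listed and 149 without the second-listed cDC library. The same settings gave 472 and 955 for the opposite pattern, and equal autosomal totals gave 398 and 481.

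The 2 lists often call such a place over different lengths, so the opposite changes are not measured over the same base pairs. On chromosome 12, a region from 25984001 to 25993200 had 8848 and 9383 in cDC against 1017 and 1075 in CDP. Inside it, a region from 25986151 to 25986500 had 0 and 14 in pDC against 90 and 134 in CDP. On chromosome 11, a region from 87056951 to 87061550 had 10728 and 12600 in pDC against 837 and 1513 in CDP, while a region from 87061201 to 87061650, which overlaps its end, had 17 and 26 in cDC against 191 and 230 in CDP. These places have the largest change of each pattern, taking the smaller of the 2 log2 ratios, and were chosen after their values were seen.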

How the results depend on the processing

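The combined rule, the removal of touching regions, adjusted p-values, equal autosomal totals, and leaving out libraries for the counts were chosen after the results were seen; the other alternatives were fixed before the data were examined. Counts are given in the order MPP and CDP, CDP and cDC, CDP and pDC, cDC and pDC.

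Stricter rules lowered the counts by construction, since each keeps part of a list. A deposited −log10 p of at least 10 left 13460 higher in MPP and 8761 in CDP, 18658 in CDP and 12737 in cDC, 17871 in CDP and 20971 in pDC, and 12566 in cDC and 22432 in pDC. A length of at least 500 bp left 20154 higher in MPP and 14553 in CDP, 22489 in CDP and 18648 in cDC, 18932 in CDP and 21611 in pDC, and 15865 in cDC and 23508 in pDC. A ratio of at least 2 left 8950 higher in MPP and 6829 in CDP, 17364 in CDP and 9245 in cDC, 15252 in CDP and 18612 in pDC, and 9007 in cDC and 18871 in pDC. The combined rule left 6745 higher in MPP and 5161 in CDP, 12450 in CDP and 6994 in cDC, 12351 in CDP and 16417 in pDC, and 7446 in cDC and 16803 in pDC. Separate libraries left 19607 higher in MPP and 16289 in CDP, 27669 in CDP and 16938 in cDC, and 17253 in cDC than pDC. Without touching regions, 21368 were higher in MPP and 15808 in CDP, and 27835 in CDP and 17403 in cDC. The other 71 counts, from these and the remaining alternatives, stayed within 1.5 times the deposited count, as did the 56 alternatives tried for the combined rule. With a library left out, the counts of all regions fell in both directions, so regions that changed side were not added to the other side. Those counts therefore say little about which side has more. For the combined rule with a library left out, the deposited p-value was still that of all 4 libraries.

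The median log2 ratio of all regions was the least stable result. At a −log10 p of at least 10 it was -0.45, -0.57, 0.55 and 0.91 in the 4 lists, further from 0 in each. With equal autosomal totals it changed sign in 3 lists, to 0.017 for CDP over MPP, -0.26 for pDC over CDP and -0.26 for pDC over cDC; the cause was not tested. With each library left out in turn, it ran from -0.23 to 0.091, from -0.44 to 0.052, from -0.083 to 0.14 and from -0.017 to 0.45. The sign changed without the first-listed MPP library (0.091), without the first-listed cDC library (0.052 over CDP and -0.017 for pDC over cDC), and for pDC over CDP without the first-listed CDP (-0.071) or second-listed pDC library (-0.083). Places higher in cDC and lower in pDC than CDP numbered 149 to 456 with each library left out.

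The overlap of lists fell under each alternative, in the order MPP and CDP with CDP and cDC, then with CDP and pDC, CDP and cDC with CDP and pDC, then with cDC and pDC, and CDP and pDC with cDC and pDC. It was 88.1%, 85.0%, 78.2%, 72.4% and 82.8% when 50% of the shorter region had to be covered, 85.4%, 81.2%, 76.6%, 70.6% and 82.6% of base pairs, and 59.9%, 65.3%, 67.1%, 54.5% and 69.3% with a −log10 p of at least 10 in both lists.

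No paired analysis was possible because the lists' values carry no replicate number. Gene lists and their alternatives were not run, since no annotation of mm9 was used, nor was a rescaling over the regions of all lists, since a list gives signals for its own regions only. The unknown read depth leaves the counting error of single regions open.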

Other observations

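All tests in this part were chosen after the results were seen. Most places that differed between cDC and pDC were also listed against CDP, but this says little about a difference from CDP. The lists state no threshold and include regions with large p-values, so being listed was nearly fixed in advance. Without the combined rule, 0.039% of the regions higher in cDC and 4.09% of those higher in pDC were in neither list with CDP. Of the 16803 regions higher in pDC under the combined rule, 54.4% were higher in pDC than CDP at places outside the CDP and cDC list, 23.0% were higher in pDC and lower in cDC than CDP, and 14.9% were higher in both. Of the 7446 regions higher in cDC, 36.2% were higher in cDC than CDP at places outside the CDP and pDC list and 32.7% were higher in cDC and lower in pDC than CDP. A further 25.1% were lower in both than in CDP, and 5.91% were higher in both. Without the combined rule the 4 shares for pDC were 27.7%, 19.7%, 28.2% and 18.7%, and the 4 for cDC were 18.2%, 26.1%, 35.1% and 20.4%. The regions were chosen with the same cDC and pDC libraries that are read against CDP here, no value for unchanged groups was computed, and the difference between cDC and pDC was not tested.

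The second-listed MPP and first-listed pDC libraries had signal in the X chromosome region and little on Y. Their Y signal was at most 3.84% of that of the other library of the group, which is consistent with libraries from animals of different sex. The bounds of this test were set after these percentages were known, and the labels give no sex. Low signal of the whole second-listed MPP library is argued against by the autosomes, where 0.048% of 52493 regions in the same range of first-library signal were at 0 in it, against 6 of 6 Y regions. The second-listed cDC library had the X region together with 32.9% of the Y signal of the first, taken over the first 1 Mb of Y. Over all Y regions the gap was wider, at 0.087% against 0.45% of autosomal signal in the CDP and cDC list. In the cDC and pDC list it was 0.094% against 0.50%. The X region together with Y signal argues against cells of 1 sex only, but the share depended on the Y regions taken. A mixed source or another cause stays open.

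The second-listed cDC library had more signal where cDC is low and pDC is high. At 1883 regions high in pDC and low in CDP it exceeded the first by a median log2 of 1.15 (95% bootstrap interval 1.08 to 1.21), and by 1.03 and 1.32 with looser and stricter choices of regions. The intervals describe spread over regions of the same 2 libraries, not spread between libraries. The offset of 1.15 is 0.48 above regions of the same cDC signal, which argues against a single scale factor. At 641 regions high in CDP and low in pDC the offset was 0.82, with an interval of 0.75 to 0.89, and 0.24 above regions of the same signal, but the 2 CDP libraries, at regions high in pDC and low in cDC, also differed by 0.24 more than at regions of the same signal. An excess of this size is thus not particular to cDC, and pDC signal alone, higher background, other cells in the sample and a difference in the cDC themselves stay open.

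Between 25.2% and 41.1% of the regions of a list touched a region of the opposite direction. Their median absolute log2 ratio was 0.26, 0.29, 0.35 and 0.30 in the 4 lists, at most 0.32 times that of the other regions, which is consistent with peaks of little difference being split into segments. A difference in peak breadth or fragment length between groups would put the flanks of touching triples higher in the same group, but the more common order held at most 61.8% of them. Under the combined rule, 1.61% to 7.71% of touching regions remained, against 31.0% to 52.4% of the others. No biological explanation was tested.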
